A study of Homo sapiens with 12 samples.

How the data were processed

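RNA sequencing of untreated, confluent primary osteoblast cultures gave 12 libraries, 9 from patients with end-stage kidney disease (group CKD) and 3 from healthy controls. Every library came from a different donor per the labels, which give no batch, and the groups were taken from the sample titles. Per the labels' protocols, RNA was extracted with the RNeasy Micro Kit and polyA libraries were made with the KAPA Stranded RNA-Seq Kit. Per the submitters' processing notes, bcl2fastq 2.17, Bowtie2 2.1.0 and RSEM 1.2.15 were used, with no role or setting stated. The genome build, the annotation, the counting strand and the tool behind the authors' comparison are not given in the sources used here, so no coordinates are printed.

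The table deposited by the authors holds 25343 genes with a value per library. The unit of these deposited values is a coverage signal, namely reads scaled per-million of an effective library size that the authors set for each library, written RPM here. Every deposited value above 0 was a whole multiple of the smallest value in its column within a tolerance of 0.01 (100% of values), so whole reads could be recovered. Column sums lay between 96.7% and 103.7% of the nominal total, so the values are not plain CPM. The authors' fold change in the same table is a signed score, positive where CKD is higher, and the authors' p-value and false discovery rate stand beside it. All columns of per-sample values were mapped to a sample by their names. A spreadsheet had turned 28 symbols into dates, and these rows were named by the long gene name beside them. No row was unnamed.

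Depth was 11.9 to 16.2 M recovered reads per library, at which 1 read is worth less than 0.1 RPM. The number of control donors limits the precision too, and its weight against counting error was not compared gene by gene. Before any test, 147 genes that can tell about a single donor were removed (genes of X inactivation, Y-linked genes, HLA genes and genes with common deletions), with chromosomes taken from a RefSeq gene table of assembly GRCh38.p14. In the full table, counted before that removal, 5280 genes had no read in any library.

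The design written before the data were examined had 1 test for counts and another for a normalized unit. Since the table holds a normalized unit, the second applied. Values were transformed to log2(value + 1), and genes with a value of at least 1 in at least 3 libraries were kept, which left 13726. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A log2 fold change is CKD minus control on the log2(value + 1) scale, which understates the change of low genes, so group means are given beside it. Means are in RPM with the SD over libraries. A fold against a group without reads was computed over a floor of 3 reads in that group.

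Gene lists were fixed beforehand, 31 in all with 933 genes. They were tested with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured genes. Skeletal muscle markers had 3 measured genes and mitochondrially encoded transcripts 0, and neither was tested. Camera with an estimated correlation, the rotation test fry and an exact permutation test of each list's mean over 220 assignments were run beside it. Spread within groups was the mean pairwise Euclidean distance over the 500 most variable genes, tested by exact permutation.

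The rule for the genes named in the text was fixed beforehand. Among genes past the threshold with a mean of at least 1, it took the 8 largest changes in each direction with full separation of the groups and the 3 of smallest p in each direction. From each list it took the 3 members of smallest p where camera passed and 1 member otherwise. A set of osteoblast, Wnt antagonist and cell cycle genes was always named. The rule gave 62 tested genes, of which 37 passed. Names of further members of a list serve to say which genes make up its count. The results of some genes are not reported here, although they remain in the counts.

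The alternatives fixed beforehand were quantile normalization, array weights, no filter, a stricter filter (at least 1 in at least 9 libraries), pseudocounts of 0.1 and 5, a block on the replicate number, leaving out each library, and a false discovery rate of 0.01 for the authors' table. Chosen after the data were seen were edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 (Wald test) on the recovered reads, DESeq2 size factors as the scaling, and the permutation of list means. The edgeR test called 621 genes, 573 of them shared with the limma result.

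The gene test was tried on simulated counts drawn from the real means and library sizes, with 200 genes changed and a list of 40 others raised together. Of 13722 genes in the simulated CKD versus control comparison, it recovered 46% of those changed 1.5-fold, 77.6% at 2-fold, 95.9% at 4-fold and 100% at 16-fold. The 179 simulated genes called were 154 of the changed genes, 19 of the raised list and 6 (3.4%) that had not been changed. Genes were drawn independently of each other, so variation shared by many genes within a library was not simulated. Figures were drawn with matplotlib 3.10.9.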

Results

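Gene expression was measured by RNA sequencing in cultures of primary human osteoblasts, the bone-forming cells that lay down type I collagen matrix. The cells came from 9 patients with end-stage kidney disease (CKD group) and from 3 healthy controls. Each culture was grown to confluence without treatment, and 1 library was made per donor. The labels give iliac crest as the tissue of the CKD cultures and trabecular bone as that of the control cultures. Labelled bone source and disease thus changed together in the design. Trabecular bone names a type of bone and no skeletal site, so a shared site is not excluded. The reads recovered from the deposited table came to 11.9 to 15.6 M per CKD library (mean 14.34 M ± 1.22, SD, n = 9). Control libraries held 14.4 to 16.2 M reads (mean 15.17 M ± 0.93, SD, n = 3), and depth did not differ between groups (exact permutation test, two-sided, p = 0.318). Between 13089 and 13363 genes reached a value of at least 1 RPM in a library, RPM being reads scaled by the authors to an effective library size. The 10 most abundant genes took 12.8% to 15.3% of the reads of a library. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom among the CKD pairs being 13.6.

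The design addresses how osteoblasts of patients with end-stage kidney disease differ from those of healthy donors. Several genes that pattern the embryo were among those of smallest p. EMX2, a homeobox gene of urogenital and limb girdle development, stood at 9.94 ± 1.22 RPM in CKD cultures (SD, n = 9) and at 0.414 ± 0.498 in controls (SD, n = 3). ZIC1, a zinc finger factor of neural and somite patterning, went the other way, at 0.392 ± 0.467 in CKD cultures and 49.3 ± 6.02 in controls. ALPL, the alkaline phosphatase needed for mineralization, and several neutrophil-attracting chemokines were lower in CKD cultures, while type I collagen did not pass the test. Of 13726 genes tested with limma, 626 passed a Benjamini-Hochberg adjusted p of 0.05, with 292 higher and 334 lower in CKD cultures. At least a 2-fold ratio of group means was reached by 279 of them, 98 higher and 181 lower. Every CKD library lay on one side of every control library in 936 of the 13726 genes (6.82%), a separation that chance gives for 0.91% of genes. It held for 527 of the 626, which were chosen for their difference. Over all genes tested the median log2 fold change was -0.004. The call rests on 3 control libraries: 191 genes passed without control replicate 1, 344 without control replicate 2 and 226 without control replicate 3.

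Homeobox and other patterning genes were among those of smallest p in both directions. EMX2 had a log2 fold change of 3.00 (SE 0.17, adjusted p = 7.32e-07). EN1, the engrailed factor of limb ventral identity, stood at 21.4 ± 5.79 RPM in CKD cultures against 2.19 ± 0.408 in controls. SHOX2, which acts in the proximal limb skeleton, stood at 11.9 ± 4.22 against 0.923 ± 1.19. ALX1, a factor of craniofacial mesenchyme, was at 5.53 ± 1.15 in CKD cultures and had no read in the 3 control libraries. It was at least 85-fold higher over a floor of 3 reads in the control group, a bound that covers counting error only. In the other direction, PKNOX2, a homeobox factor of the TALE class, stood at 0.711 ± 0.439 against 31.5 ± 4.84. ZIC4, the neighbour of ZIC1, stood at 0.293 ± 0.241 against 11.5 ± 3.33. ZIC1 had a log2 fold change of -5.23 (SE 0.24, adjusted p = 1.14e-07). EMX2 overlaps its antisense partner EMX2OS, and the counting strand is not given in the sources used here, so the reads of that pair cannot be assigned to either with certainty.

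**Figure D1:**
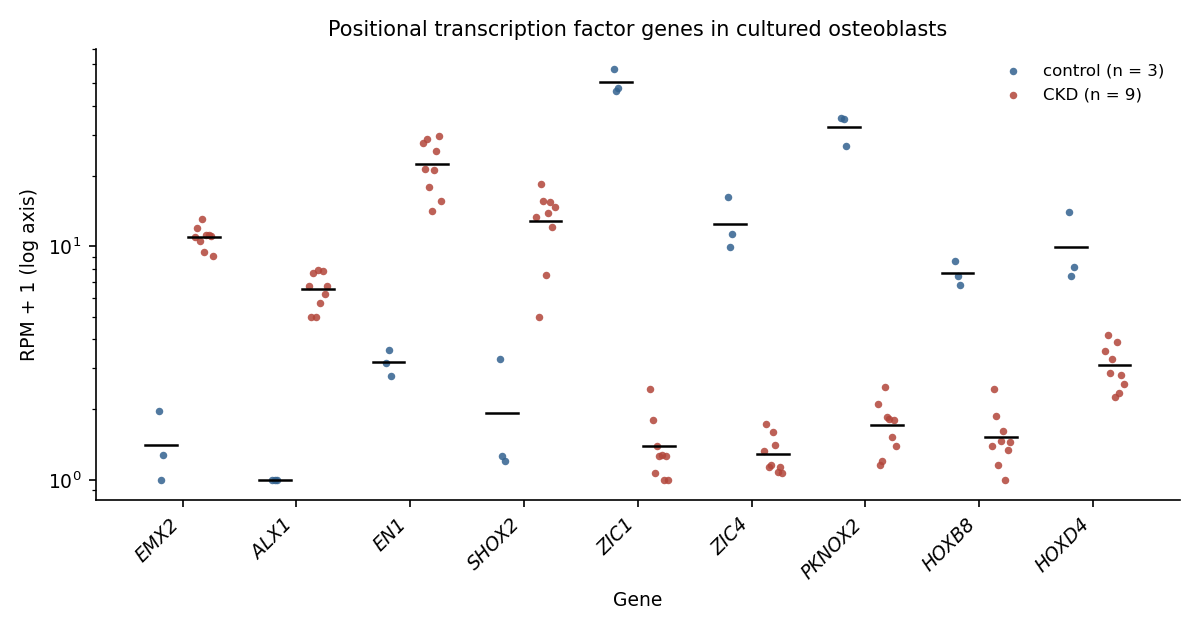
RPM plus 1 (log axis) of 9 patterning genes in each library of the control (blue, n = 3) and CKD (red, n = 9) groups, with the group mean as a black line. EMX2 averaged 9.94 RPM in CKD and 0.414 in control libraries, and ZIC1 0.392 and 49.3, with no overlap between the groups in any of the 9 genes. Several of the 9 were named by a rule that required such separation.

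Among the HOX and limb position genes, a list fixed in advance, 33 were measured, of which 5 were higher and 11 lower in CKD cultures. Adjusted over the list alone, 10 were higher and 14 lower. HOXB8 fell from 6.66 ± 0.929 in controls to 0.528 ± 0.428 RPM in CKD cultures (adjusted p = 8.93e-05). HOXD4 was lower as well, at 2.09 ± 0.679 against 8.89 ± 3.62 (adjusted p = 0.00152). PITX1, a hindlimb factor, and HOXA10, HOXA11 and HOXC11 were among the higher genes, with log2 fold changes of 2.73, 0.53, 0.70 and 1.14. The list passed camera in the lower direction (adjusted p = 0.0387), a call lost with an estimated correlation (adjusted p = 0.87). It was also lost without the low-value filter (adjusted p = 0.0701), and without control replicate 1 (0.866), 2 (0.174) or 3 (0.584). The 4 CKD libraries whose removal ended it too gave adjusted p of 0.0587, 0.0599, 0.0531 and 0.0692 without CKD replicate 1, 5, 7 and 9.

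Few bone matrix and differentiation genes passed. Of 19 osteoblast differentiation genes measured, ALPL alone passed, at 36.2 ± 34.1 RPM in CKD cultures against 281 ± 119 in controls (log2 fold change -3.34, SE 0.69, adjusted p = 0.0188). Its call was lost without control replicate 1, 2 or 3 (adjusted p = 0.0663, 0.0867 and 0.0694), with its log2 fold change between -3.62 and -2.95 over all settings tried. COL1A1, the main chain of type I collagen, gave 30050 ± 5714 against 31000 ± 5404 (adjusted p = 0.91). RUNX2, the master factor of the lineage, gave 35.5 ± 7.80 against 45.7 ± 1.91 (adjusted p = 0.255). IBSP gave 4.32 ± 2.89 against 2.11 ± 1.09, and SPP1 gave 6.46 ± 4.86 against 9.03 ± 3.30, neither past the threshold. SP7 and FGF23 were listed at 0 in all 12 libraries. BGLAP, whose reads overlap a readthrough transcript, and TNFSF11 lay below the filter, with group means from 0.0667 to 0.76 RPM. None of the 14 mineralization and osteocyte genes passed, while adjusted over the list alone 3 were lower and 0 higher. MGP, an inhibitor of calcification, averaged 17.7 ± 14.4 against 70.1 ± 23.5 (adjusted p = 0.0547), and DKK1, a Wnt antagonist, 94.3 ± 45.2 against 44.3 ± 15.8 (adjusted p = 0.182). By camera, the adjusted p was 0.454 for the osteoblast list and 0.48 for the mineralization list. Their mean log2 values differed by -0.286 and -0.307 between CKD and control libraries (exact permutation p = 0.0273 and 0.0455, both 0.176 after adjustment over 29 lists). MGP passed the threshold without CKD replicate 4 or 7 (adjusted p = 0.0298 and 0.0282), with array weights (0.0273), at a pseudocount of 5 (0.0397) and with DESeq2 on recovered reads (0.0441).

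**Figure D2:**
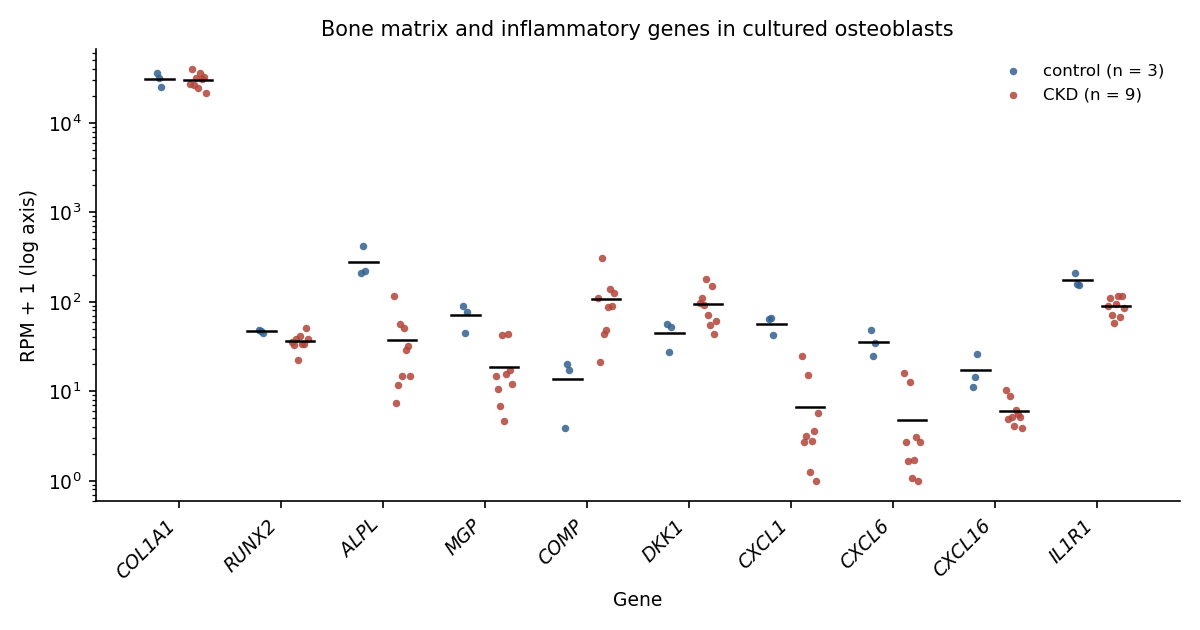
RPM plus 1 (log axis) of 10 bone matrix and inflammatory genes in each control (blue, n = 3) and CKD (red, n = 9) library, with group means as black lines. COL1A1 averaged 31000 in control and 30050 in CKD libraries, ALPL 281 and 36.2, and CXCL1 56.2 and 5.72 RPM.

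Several chemokine genes were lower in CKD cultures. Of 30 inflammatory cytokine and chemokine genes measured, 8 were lower and 0 higher, and adjusted over the list alone 13 were lower. CXCL1 and CXCL6, which draw neutrophils, averaged 5.72 ± 8.10 and 3.75 ± 5.60 RPM in CKD cultures (SD, n = 9) against 56.2 ± 12.8 and 34.9 ± 11.8 in controls (SD, n = 3). CXCL16 stood at 5.03 ± 2.18 against 16.3 ± 7.83, and IL1R1, the interleukin 1 receptor, at 88.9 ± 21.8 against 174 ± 31.4. Their log2 fold changes were -3.83 (SE 0.82), -3.58 (SE 0.78), -1.50 (SE 0.31) and -0.99 (SE 0.21), with adjusted p of 0.0216, 0.0232, 0.0172 and 0.0196. The other lower genes were CXCL2, CXCL3, CXCL5 and TNFAIP6. Leaving out control replicate 1, 2 or 3 ended the calls of CXCL1 (adjusted p = 0.0959, 0.0809 and 0.0724), CXCL6 (0.113, 0.0605 and 0.0905) and IL1R1 (0.116, 0.0544 and 0.0612), and CXCL16 lost its call without control replicate 2 (0.0501) or 3 (0.102). The list passed camera in the lower direction (adjusted p = 1.61e-07) but not with an estimated correlation (adjusted p = 0.87). Its mean log2 value was 3.48 ± 0.406 in CKD and 4.40 ± 0.0372 in control libraries. An exact permutation test gave p = 0.00909, the smallest that 220 assignments allow, or 0.176 after adjustment over 29 lists. After that adjustment no list could pass unless at least 6 lists had a small p. The 40 interferon response genes held no call (camera adjusted p = 0.0571), although the list passed without 6 of the 12 libraries in turn, with adjusted p down to 0.00179. With all 12 libraries its adjusted p was 0.979 with an estimated correlation and 0.829 in the exact permutation test of the list mean. The member IRF1 averaged 24.8 ± 2.21 against 32.4 ± 5.84 and passed without CKD replicate 9 (0.0489) or control replicate 2 (0.0255). Blood cell and osteoclast markers held no call among 8 measured (adjusted p = 0.945), LAPTM5 averaging 6.20 ± 5.72 against 0.904 ± 0.326.

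Cholesterol synthesis and cell division lists had mostly positive log2 fold changes, with no member past the all-gene threshold when all 12 libraries entered limma. Of 25 cholesterol synthesis genes measured, 24 had a positive log2 fold change with a median of 0.43, and 6 were higher when adjusted over the list alone. MSMO1, an enzyme of the late sterol pathway, gave 109 ± 22.6 against 64.2 ± 17.2 RPM (adjusted p = 0.056 over all genes). STARD4, a sterol carrier, gave 27.5 ± 4.58 against 18.2 ± 3.96, and IDI1, an isomerase of the isoprenoid branch, 52.1 ± 8.89 against 35.1 ± 6.08. Without CKD replicate 1 these 3 genes passed (adjusted p = 0.0223, 0.0406 and 0.0152), as they did with DESeq2 on recovered reads (0.00658, 0.0142 and 0.0129). MSMO1 also passed without CKD replicate 4 (0.0398) and STARD4 without CKD replicate 7 (0.0282). Camera gave an adjusted p of 1.61e-07, lost with an estimated correlation (adjusted p = 0.87). In an exact permutation test of the list mean, p was 0.0364, or 0.176 after adjustment. Of 50 proliferation genes, 49 had a positive log2 fold change with a median of 0.21, and 0 passed, also adjusted over the list alone. CDC45, CDC6 and MELK had log2 fold changes of 0.52, 0.48 and 0.35 (adjusted p = 0.161, 0.25 and 0.254). MKI67, the usual marker of cycling cells, averaged 194 ± 57.5 against 167 ± 20.0 (adjusted p = 0.824). Camera gave the proliferation list an adjusted p of 0.00064, lost with an estimated correlation (adjusted p = 0.979) and without control replicate 3 (0.0628). The cell cycle inhibitors CDKN1A (426 ± 111 against 412 ± 106) and CDKN2A (33.3 ± 15.6 against 32.6 ± 2.15) did not pass.

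Signalling lists held calls in both directions, and none passed camera. LTBP2, a matrix protein that associates with fibrillin, gave 1988 ± 344 against 1050 ± 140 RPM (adjusted p = 0.00499) and was 1 of 3 higher and 2 lower among 44 BMP and TGF-beta genes (camera adjusted p = 0.772). WNT5B, a non-canonical Wnt ligand, gave 166 ± 54.1 against 52.7 ± 20.3 (adjusted p = 0.00722; 0.0525 without control replicate 1). With it WNT7B was higher and WNT16, SFRP4 and ROR2 lower, among 37 Wnt genes (camera adjusted p = 0.945). Of 15 Notch genes, RFNG passed at 57.2 ± 3.57 against 47.5 ± 3.09 (camera adjusted p = 0.95 for the list). Its call was lost without 10 of the 12 libraries in turn, with adjusted p up to 0.201. Of 26 immediate early genes, 6 were higher, namely DUSP5 (12.4 ± 1.19 against 7.17 ± 1.67, adjusted p = 0.00558), KLF2, JUND, CYR61, KLF6 and NR4A1 (camera adjusted p = 0.179). EFNB2, an ephrin of the osteoblast to osteoclast dialogue, gave 39.1 ± 5.84 against 21.2 ± 6.83 and was the only call among 18 osteoclast coupling genes (camera adjusted p = 0.277), lost without control replicate 1 (0.0797). Adjusted over the coupling list alone, 1 gene was higher and 4 were lower. TNFRSF11B, the decoy receptor osteoprotegerin, averaged 183 ± 61.9 against 213 ± 95.9 (adjusted p = 0.849), and SFRP1 1.28 ± 1.21 against 2.24 ± 0.959 (adjusted p = 0.402). None of 12 mineral hormone genes passed (camera adjusted p = 0.945), GNAS giving 787 ± 51.8 against 665 ± 12.4. GADD45B (63.1 ± 10.5 against 37.2 ± 13.6) was 1 of 2 higher genes among 26 senescence and p53 targets (camera adjusted p = 0.80). GADD45B lost its call without CKD replicate 8 (0.0523), control replicate 1 (0.151) or control replicate 3 (0.164).

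Matrix, stress and metabolic lists held fewer calls. ADAMTS5, an aggrecan-cleaving protease, fell to 41.7 ± 12.8 in CKD cultures against 117 ± 26.1 RPM (adjusted p = 0.00975; 0.0651 without control replicate 3). LOXL3 was the other lower gene of 39 matrix remodelling genes (camera adjusted p = 0.952). COL21A1 was the only call of 27 collagen genes (0.488 ± 0.55 against 5.94 ± 5.07, camera adjusted p = 0.95 for the list). Among 30 oxidative stress and NRF2 targets, 4 were lower and 0 higher (camera adjusted p = 0.141). GCLC, the rate-limiting enzyme of glutathione synthesis, stood at 10.9 ± 1.32 against 24.3 ± 3.34 (adjusted p = 0.000182), beside ABCC1, AKR1C1 and SOD3. Of 32 glycolysis and hypoxia genes, ADM (20.2 ± 7.93 against 66.3 ± 22.5) and HK2 were lower (camera adjusted p = 0.95). The ADM call was lost without control replicate 1 (0.101) or 2 (0.0735). Of 18 clock genes, NPAS2 (11.4 ± 4.25 against 28.5 ± 7.00) and ARNTL were lower and BHLHE40 higher (camera adjusted p = 0.95). NPAS2 lost its call without control replicate 1, 2 or 3 (0.134, 0.0824 and 0.0577). No member passed among 46 oxidative phosphorylation genes, 28 endoplasmic reticulum stress genes, 47 cytosolic ribosomal protein genes and 6 histone genes, with camera adjusted p of 0.95, 0.863, 0.95 and 0.945. Their members of smallest p, UQCRB, ATF6, RPS23 and HIST1H2BD, had log2 fold changes of -0.22, -0.15, 0.15 and -0.33. UQCRB passed without CKD replicate 7 (adjusted p = 0.0498) and with DESeq2 on recovered reads (0.031).

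Markers of other cell types differed gene by gene. COMP, a cartilage and tendon matrix protein, stood at 107 ± 85.3 in CKD cultures against 12.7 ± 8.65 RPM, and MATN3 at 4.94 ± 1.67 against 1.65 ± 0.444, while PRG4 was lower, among 11 chondrocyte markers (camera adjusted p = 0.122, and 0.00239 or 0.00428 without control replicate 2 or 3). With all 12 libraries that list's adjusted p was 0.87 with an estimated correlation and 0.176 in the exact permutation test of the list mean. The COMP call (adjusted p = 0.034) was lost without any control library, with adjusted p of 0.184, 0.057 and 0.0799, and without 5 of the CKD libraries, with adjusted p up to 0.0551. MATN3 lost its call without control replicate 1 (0.101) or 3 (0.063). ACTG2, a smooth muscle actin, stood at 0.715 ± 0.498 against 48.5 ± 39.9 (adjusted p = 3.09e-05). RGS5 was lower too, and MCAM and TPM1 higher, among 21 smooth muscle and myofibroblast markers (camera adjusted p = 0.952). NEFM, a neurofilament chain, stood at 0.68 ± 0.602 against 22.1 ± 24.9, with TUBB3 higher, among 9 epithelial and neural markers (camera adjusted p = 0.863). EGFL7 (4.39 ± 1.47 against 1.17 ± 0.503) was higher and PECAM1 lower among 5 endothelial markers (camera adjusted p = 0.588). EGFL7 lost its call without control replicate 2 (0.057) or 3 (0.0677). None of 10 adipocyte markers passed (camera adjusted p = 0.952), AGPAT2 giving 25.2 ± 2.06 against 21.1 ± 1.10. The BMP and TGF-beta, mineral hormone, matrix remodelling, collagen, smooth muscle, epithelial and neural, adipocyte and ribosomal lists differed in sign between their median, their mean and camera's direction. Outside the lists, the CKD cultures had more FLG, the epidermal filaggrin (394 ± 400 against 16.0 ± 10.1), LRRC15, a mesenchymal surface protein (141 ± 107 against 20.9 ± 19.1), and SCIN, an actin-severing protein (13.0 ± 9.88 against 0.543 ± 0.0757). They had less IGFN1 (0.106 ± 0.102 against 41.6 ± 39.6), IGFBP1, an insulin-like growth factor binding protein (0.365 ± 0.294 against 52.6 ± 53.1), and ADAMTS15 (1.60 ± 1.02 against 36.4 ± 32.7). The adjusted p for these 6 genes lay between 1.09e-05 and 0.0178. FLG lost its call without control replicate 1 (0.055) or 3 (0.0675), and LRRC15 without control replicate 2 (0.0574) or 3 (0.0964).

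The libraries separated by group along the first principal component of the 500 most variable genes, which held 40.2% of their variance. The test of spread between donors cannot decide whether the groups differ in it. Its permuted splits mix the groups, so the larger distance between groups enters them. The mean pairwise distance on the log2 scale was 28.8 over 36 CKD pairs and 30.4 over 3 control pairs, a difference of -1.56 (exact permutation test over 220 assignments, two-sided, p = 0.982). Between groups the mean distance was 42.2. Without control replicate 1 the difference was 1.33.

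**Figure D3:**
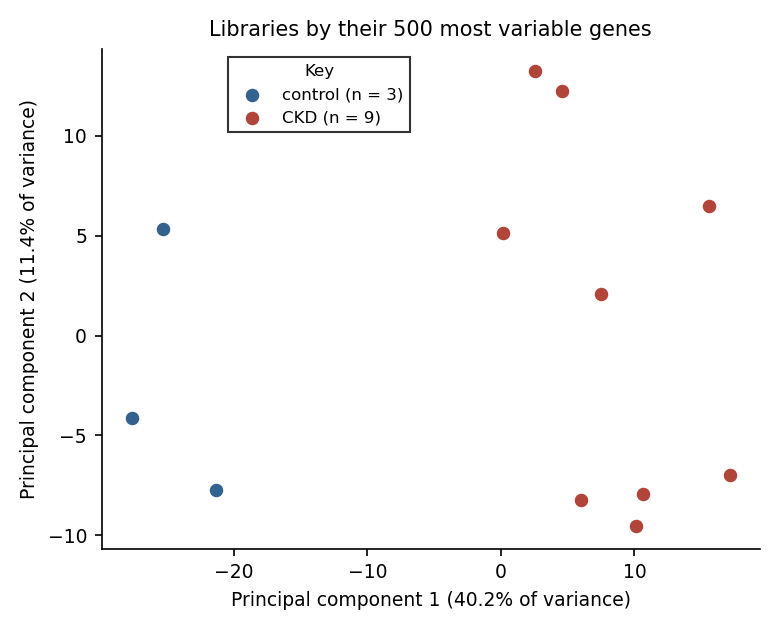
Each point is a library placed by the first 2 principal components (percent of variance on each axis) of its 500 most variable genes, control in blue (n = 3) and CKD in red (n = 9). Control libraries lie between -27.6 and -21.3 on component 1, and CKD libraries between 0.12 and 17.1.

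The authors' deposited table gives its own comparison, with 856 genes at a false discovery rate under 0.05, of which 356 were higher and 500 lower in CKD. Of those 856 in the authors' deposited table, 736 entered the test here, 470 passed it as well, and all 470 had the same direction. At a rate under 0.01 the authors' deposited table holds 541 genes, 202 higher and 339 lower. The authors' deposited table gives ZIC1 a signed fold change of -123.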

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

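The tests of HOX gene number and of summed blood cell transcripts, and the enrichment of homeobox names with its counts without each library, were chosen only after the result was seen. Among 96 measures examined within the CKD group (62 named genes, 29 list means and 5 library measures), 3 had 1 library far from the other 8. Chance sets apart about 1 in 20 such groups. For COL21A1 the gap of the highest library to the next was 0.529 of the range, with a log2 value of 1.52 against 0.18 to 0.809 in the others. For ADAMTS5 the lowest library stood apart by 0.504 of the range, at 4.31 against 5.15 to 5.99. The mean of the endothelial markers stood apart by 0.55 of the range in its lowest library, at 1.80 against 2.27 to 2.65.

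Homeobox genes were over-represented among the genes that differed: of 108 tested genes with homeobox or homeodomain in their name, 25 passed (23.1%), 12 higher and 13 lower, against 601 of 13618 other genes (4.41%). The odds ratio was 6.52 (95% interval 3.96 to 10.4, Fisher's exact test, p = 1.14e-11). The test takes genes as independent, which genes measured in the same 12 libraries are not, so the interval may be too narrow. Without control replicate 1 the odds ratio was 9.63 and 12 of these genes passed, against 17 to 25 genes without each of the others. Without each library in turn the odds ratio lay between 5.91 (CKD replicate 7) and 13.3 (control replicate 3). A mislabelled library is argued against, since 0 of the 12 libraries lay nearer the mean of the other group when the homeobox genes were chosen without it. Bone source and kidney disease cannot be told apart as origins of the pattern, because every CKD culture came from the iliac crest and every control culture from a source labelled trabecular bone. Other cell types stay open too, since the highest group mean among 10 endothelial, blood, epithelial and glial markers was 2.52 RPM (PECAM1 in controls), between the bounds of 1 and 5 set beforehand, and other mesenchymal cells would not be seen with these markers.

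The mean log2 value of inflammatory genes differed by -0.915 between CKD and control libraries. Dependence of that mean on a particular control library is argued against, as the difference stayed between -0.933 and -0.896 without each control in turn. Blood cells in the control cultures stay open, since the bound set against them beforehand was missed. That bound was a control mean under 1 RPM for each of 5 blood cell transcripts, and CSF1R stood at 1.90. None of the 5 had a higher mean in controls, however. CSF1R averaged 2.79 in CKD libraries, and TYROBP 0 in both groups. PTPRC averaged 0.32 in CKD and 0.234 in control libraries, FCER1G 0.367 and 0.242, and LAPTM5 6.2 and 0.904. CD14, which is not among the 5, went the other way. The sum of PTPRC, TYROBP, FCER1G, LAPTM5 and CSF1R was 9.67 ± 4.97 in CKD (n = 9) and 3.28 ± 0.849 in control libraries (n = 3), a difference of 6.39 (exact permutation p = 0.00909, the smallest possible), but LAPTM5 alone gave 5.29 of it, and the exact permutation p was 0.218 without LAPTM5 and 0.364 with CD14, which averaged 5.23 ± 2.46 in controls and 2.09 ± 1.23 in CKD libraries. The difference was 1.1 without LAPTM5 and 3.25 with CD14. With CD14 and without LAPTM5 it turned to -2.04 (exact permutation p = 0.209). Kidney disease and bone source both remain open, untested.

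Cholesterol synthesis genes had a mean log2 value higher by 0.446 in CKD libraries (95% interval of a linear model 0.037 to 0.855). Scaling by the authors is argued against, since the difference was 0.455 after quantile normalization and 0.446 with DESeq2 size factors. A higher share of dividing cells cannot be told apart from a difference between the groups: with the proliferation mean of each library as a covariate the difference was 0.35 with an interval of -0.052 to 0.752, which holds both 0 and the unadjusted size. The exact permutation p of the list mean was 0.0364 before adjustment over the lists and 0.176 after it. No list could pass after adjustment unless at least 6 lists had a small p. Kidney disease and bone source stay open, untested.

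Chance is argued against for the number of genes past the threshold. It is not excluded, since 1 in 100 is the smallest share these splits allow. Of 100 splits of the 12 libraries into 9 and 3, the real one included, 1 split (the real one) called as many as 626 genes, and the highest of the others called 11. Those other splits mix the groups, so the difference between groups adds to their residual variance and can lower their counts. The splits do not argue against chance for the number of gene lists passing camera at the preset correlation. There 80 of the 100 splits called at least as many as the real 4 lists, and the highest of the others called 13. The median of the other splits was 6 lists.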

How the results depend on the processing

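The edgeR and DESeq2 tests on recovered reads, DESeq2 size factors as the scaling of genes and lists, and the permutation of list means were chosen only after the data were seen. The count of 626 genes lay between 508 and 776 under quantile normalization, array weights, both other filters, both other pseudocounts, DESeq2 size factors and edgeR on recovered reads. DESeq2 on recovered reads called 1209 genes, 604 higher and 605 lower, of which 622 were shared with the 626 (the cause was not tested). Leaving out each library gave 191 to 621 genes, 83 to 285 higher and 108 to 336 lower, with 191 without control replicate 1, 344 without control replicate 2 and 226 without control replicate 3, where fewer samples enter. The 4 gene lists past the threshold were 3 to 5 without each library. With an estimated correlation and with fry for a change in 1 direction the number of lists was 0. It was 0 with the permutation of list means too. In that test the smallest p is 0.00909, and no list could pass unless at least 6 lists had a small p. Adjusted p in these 3 tests were 0.979, 0.879 and 0.562 for proliferation, 0.87, 0.0548 and 0.176 for inflammatory genes, 0.87, 0.241 and 0.176 for cholesterol synthesis, and 0.87, 0.0548 and 0.176 for HOX and limb position genes. Fry's mixed form, which takes changes in either direction, gave adjusted p of 0.389 for proliferation and 5.98e-05 for inflammatory genes. It gave 0.0308 for cholesterol synthesis and 2.83e-10 for HOX and limb position genes. Lists that did not pass camera also passed the mixed form, such as oxidative stress (4.17e-09). Without the filter the HOX list gave 0.0701 (the cause was not tested). Without each library its adjusted p ranged from 0.0202 to 0.866, that of proliferation from 8.5e-08 to 0.0628, that of inflammatory genes from 4.23e-09 to 9.1e-05 and that of cholesterol synthesis from 2.42e-11 to 0.000137. The interferon list passed with quantile normalization (0.0256), without control replicate 2 (0.0205) or 3 (0.00559), and without CKD replicate 1 (0.00806), 3 (0.00179), 6 (0.041) or 7 (0.0246). Chondrocyte markers passed without control replicate 2 (0.00239) or 3 (0.00428). With all 12 libraries and an estimated correlation, camera gave an adjusted p of 0.979 for the interferon list and 0.87 for chondrocyte markers. The spread difference ranged from -3.53 to 1.33 without each library, and its sign changed without control replicate 1. The authors' deposited table held 541 genes at a false discovery rate of 0.01 against 856 at 0.05. Of the 37 named genes past the threshold, 20 kept their call without each library, 17 lost it without at least 1 library, and 0 changed direction under any setting tried. With other settings, CXCL1 and CXCL6 lost their calls at a pseudocount of 0.1 (adjusted p = 0.0697 for both) and with edgeR on recovered reads (0.0523 and 0.0743), LRRC15 and COMP with edgeR (0.0595 and 0.0585), CXCL6 with DESeq2 on recovered reads (0.145) and RFNG without the filter (0.0521). Beside the gains given with MGP and the cholesterol genes, DESeq2 on recovered reads added IRF1 (0.0172), GNAS (0.00482), UQCRB (0.031) and LAPTM5 (0.00102), and a pseudocount of 0.1 added LAPTM5 (0.0499).

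The replicate numbers do not pair patients with controls. Deviations from the group mean correlated at 0.002, -0.016 and 0.021 between libraries of the same number, and at up to 0.138 between different numbers. A fit with the replicate number as a block called 1 gene, 1 higher and 0 lower, since 6 CKD libraries without a partner then carry no information on the difference. Of the 37 named genes, 36 lost their call in it with 0 changes of direction, the HOX list gave 0.298, and chondrocyte markers passed (0.0281). Without the block the camera adjusted p of the chondrocyte markers was 0.122, and 0.87 with an estimated correlation.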

Other observations

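The tests in this part were chosen only after the result was seen. Words in the deposited gene names were compared between the genes past the threshold and the other genes tested (551 words held by at least 10 genes, Fisher's exact test, Benjamini-Hochberg adjustment). This test too takes genes as independent, which genes measured in the same libraries are not. Of 19 genes with chemokine in their name, 7 differed and all 7 were lower in CKD cultures (odds ratio 12.3, 95% interval 4.10 to 34.1, adjusted p = 0.00341). The count was 2, 1 and 2 without control replicate 1, 2 and 3, with odds ratios of 10.2, 2.58 and 7.99, so it rests on the 3 control libraries. Calls over all genes fell too, from 626 to 191, 344 and 226. Having fewer controls and depending on a particular library thus cannot be told apart here. Beside the CXCL genes already given, the 7 chemokine genes include ACKR4, a scavenging chemokine receptor, at 0.412 ± 0.214 RPM in CKD cultures (SD, n = 9) and 2.75 ± 2.54 in controls (SD, n = 3). Of 12 genes with secreted in their name, 5 differed (adjusted p = 0.0207), and 2, 3 and 3 without control replicate 1, 2 and 3. SFRP4, a secreted Wnt modulator, gave 48.8 ± 19.8 against 129 ± 50.9, SEMA3C, an axon guidance cue, 310 ± 37.2 against 540 ± 139, and SEMA3E 2.29 ± 0.38 against 5.35 ± 1.80. SECTM1 was lower as well, and FSTL3, an activin-binding protein, was the higher one at 57.3 ± 17.5 against 28.3 ± 6.40. Homeobox was the other over-represented word (adjusted p = 3.12e-08), and the words protein and complex were under-represented (adjusted p = 0.0207 and 0.0347).

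Words that did not pass that test included receptor (37 of 466 genes differed, adjusted p = 0.0798) and ligand (7 of 39, 0.0855). Phosphodiesterases, with a larger adjusted p, did not pass it either (6 of 32 genes differed, adjusted p = 0.127, and 2, 3 and 2 without control replicate 1, 2 and 3). The members past the gene threshold included PDE1A (1.45 ± 1.08 against 14.5 ± 4.83 RPM), PDE7B (10.6 ± 2.29 against 30.6 ± 8.15), PDE1C (21.7 ± 5.99 against 41.9 ± 5.43) and PDE4D (2.75 ± 0.662 against 5.56 ± 1.48), enzymes that break down cyclic nucleotides, all of them lower in CKD cultures. GDPD1, an enzyme of another kind, was lower too. PDE11A, again a cyclic nucleotide phosphodiesterase, was higher at 3.80 ± 2.82 against 0.304 ± 0.0384.

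A hypothesis was that the HOX genes differ by paralogue number, which follows position along the body axis, as cultures from different bones might. The tissue label of the control cultures names no skeletal site, so whether the bones differed is not known. Of 24 tested HOX genes numbered 9 or lower, 10 were lower and 0 higher in CKD cultures. Of 4 numbered 10 or higher, 3 were higher and 0 lower. The 10 were 5 without control replicate 1 or 3, and without CKD replicate 1 or 6 there was 1 higher gene among the 24. The 3 were 0 without control replicate 1, 1 without control replicate 2 or CKD replicate 1, 3, 6 or 8, and 2 without CKD replicate 2, 4 or 7. Over all 28 genes, which are not independent replicates, the log2 fold change had a Spearman's rho of 0.345 with the number (100000 permutations, p = 0.072) and a Pearson's r of 0.299 (p = 0.12). The trend did not pass the test, and the hypothesis stays open.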
